A study of Mus musculus with 6 samples.

How the data were processed

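The samples were 6 preparations of choroid plexus epithelium from whole mouse brain, 3 described as wild type B10.PL and 3 as RAG-/- on the same strain, each measured on 1 single-colour oligonucleotide array from total RNA. The deposited table held 1 linear intensity per probe set and array, for 45101 probe sets. The labels state neither the software nor the normalization behind these intensities, which are not given in the sources used here. From the values, each array had a mean of 500 after the lowest and highest 2% of probe sets were set aside, so the deposited intensities had been scaled array by array, and values ran down to 0.0791, so dim probe sets had been neither floored nor removed. Such scaling makes the arrays comparable in overall brightness only. A ratio of dim probe sets depends on the background estimate.

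Groups were taken from the sample descriptions. For 1 pair of samples the description says that the samples had been reversed, and it contradicts the genotype in the titles of both. The description was used for the main comparison, and the genotype in the titles for an alternative. Both choices were fixed before the data were examined, as were the test, the threshold, the filter, the gene lists and the rule for naming genes. Where a genotype is given without further remark, it is the one in the description, and each array is named by that group and its replicate number. Nothing in the labels says whether each preparation came from a separate animal or a pool, so the p-values measure the spread between these samples, which may be partly technical.

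The 64 control probe sets were left out. Values were taken as log2(intensity + 16), so that a fold change of a dim probe set is understated. The 75th percentiles of the arrays differed by 0.232 on the log2 scale, over the limit of 0.2 set in advance, and the arrays were therefore quantile normalized. As deposited, the median difference between the groups was -0.024. Probe sets in the lowest 40% of mean log2 value were left out, which left 27022. Of the 45037 probe sets other than controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unnamed here, and 34741 of those with 1 symbol matched the mouse gene table of assembly GRCm38.p6 by gene number. That table served for symbols, chromosomes and the order of neighbouring genes. No probe set with several symbols was named. For each gene the probe set with the highest mean stood for the gene, which gave 13537 genes.

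Differences, RAG-/- minus wild type, were tested with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Of the 35 gene lists fixed in advance, 29 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, with adjustment over the lists. Of the 717 genes in the lists, 713 were found in the gene table. Rag1 and Rag2 were tested before the filter on dim probe sets, and exact permutation tests of 3 against 3 arrays, two-sided, cannot go below p = 0.1. These permutation tests ignore the pairs described below. For 3 pairs the smallest possible p of a sign test is 0.25.

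Genes were named by a rule. It took, in each direction, the 12 genes past the threshold with the largest change whose 3 RAG-/- arrays all lay on one side of the 3 wild type arrays, followed up to 12 by those with the smallest p, then Rag1 and Rag2, the 4 members with the smallest p of each list past the threshold and at most 2 of other lists described, 10 fixed genes, and list members past the threshold adjusted over the list alone. Of the fixed genes, Igkc and Hbb-b1 had no probe set with a single symbol. Applying the rule to the groups by title as well was decided after the data had been seen, and so were the added values of Cd59a, Pttg1 and the Y-linked genes by array. Any other gene is said to have been chosen after its values were seen.

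A code in the titles is shared by 1 sample of each genotype, which gives 3 pairs. Deviations from the group means correlated at 0.29, 0.39 and 0.58 within the pairs, each above the limit of 0.1, and between -0.42 and 0.01 across pairs. The codes were therefore taken to pair the samples, and a fit with the pair as a block was made beside the fit without it. In all, 4 fits were made, by description and by title, each with and without the block. The fit by title with the block was chosen after the data had been seen.

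The fit was tested on simulated data for the comparison of RAG-/- with wild type over 27022 probe sets, and the answer depended on how the noise was drawn. With each probe set's own residual SD and no block, 0% of changes of 1 log2 unit, 29% of changes of 2 and 55.9% of changes of 3 were recovered, and with the block 0% of each. That first simulation was followed by another with the moderated SD of limma, in which the recovered shares were 1.4%, 54.2% and 94.1% without the block and 18.4%, 88.5% and 96.8% with it. The second choice of noise was made after the first result had been seen, and it is the more favourable. Of 26822 unchanged probe sets, 4 and 0 were called in the first simulation and 3 and 12 in the second, without and with the block. A list of oligodendrocyte genes shifted by 1 log2 unit was called in all 4 simulations, and of the 28 lists not shifted 1 was called in 1 of them. The simulated noise was independent between genes, which that of tissue pieces need not be.

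The alternatives were a pseudocount of 1 or 64, no filter or the lowest 60% left out, the values as deposited, a common median, other variance models, array weights, the block, each array or the reversed pair left out, groups by title, an estimated correlation, and the mean of a gene's probe sets. Leaving out pair 2, pair 3 or the arrays with Y-linked signal was added after the data had been seen. Where arrays were left out under the groups by title, they keep the names that the descriptions give them. The number of arrays limits the precision of every value.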

Results

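Gene expression was measured in choroid plexus epithelium, the secretory tissue of the brain ventricles that makes cerebrospinal fluid, from wild type B10.PL mice and from RAG-/- mice of that strain. RAG1 and RAG2 together cut and join antigen receptor genes, and mice without either lack mature T and B cells. The labels do not say which of these genes was disrupted. By the descriptions there were 3 wild type and 3 RAG-/- arrays, in 3 pairs. The median deposited intensity was between 77.8 and 97.1 per array, and correlations between arrays over probe sets, which are not independent replicates, were between 0.853 and 0.969. RAG-/- replicate 2 stood apart from the other arrays, at 106 on the first principal component, which held 48.4% of the variance, where the others lay between -69.3 and 31.2. Ttr, the thyroid hormone carrier that marks this epithelium, was at 14.77 ± 0.06 (SD, n = 3) in wild type and 14.74 ± 0.08 (SD, n = 3) in RAG-/- on the log2 scale at its brightest probe set. That probe set lay at the 100 percentile, where quantile normalization leaves little room for differences. The most variable Ttr probe set ran from 13.40 to 14.74. Similar Ttr values therefore do not show equal epithelial content.

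The targeted genes were examined first, as a check of the labels. Rag1 was dim, at the 27.1 percentile of all probe sets, and was not lower in the arrays labelled RAG-/-. Its log2 value was 5.94 ± 1.20 (SD, n = 3) in the arrays labelled RAG-/- and 5.02 ± 1.32 (SD, n = 3) in those labelled wild type, a difference of 0.93 (exact permutation p = 0.3, two-sided, where 0.1 is the smallest possible). The values parted by the titles. They were 6.54, 6.92 and 6.31 in the libraries titled RAG, namely WT replicate 1, RAG-/- replicate 2 and RAG-/- replicate 3, and 4.60, 4.16 and 4.35 in the remaining arrays, a difference of 2.22 (exact permutation p = 0.1). The mean signal was higher, not lower, in RAG-/- arrays under either reading. By description the groups overlapped, and RAG-/- replicate 1 (4.60) lay below WT replicate 1 (6.54). Where the probe set lies relative to the disrupted part is not known here, so a loss of signal could not be used as a check. In pairs 2 and 3 title and description give the same genotype, and Rag1 was higher in the RAG-/- array. In pair 1 it was higher in the array titled RAG, which goes with the titles. A dim probe set in so few pairs does not settle which reading is right. Rag2 was at the 26.2 percentile and differed by 0.05 by description (exact permutation p = 1) and by -0.68 by title (exact permutation p = 0.6). All directions below therefore refer to libraries as labelled, and the reading by title is given beside that by description.

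**Figure D1:**
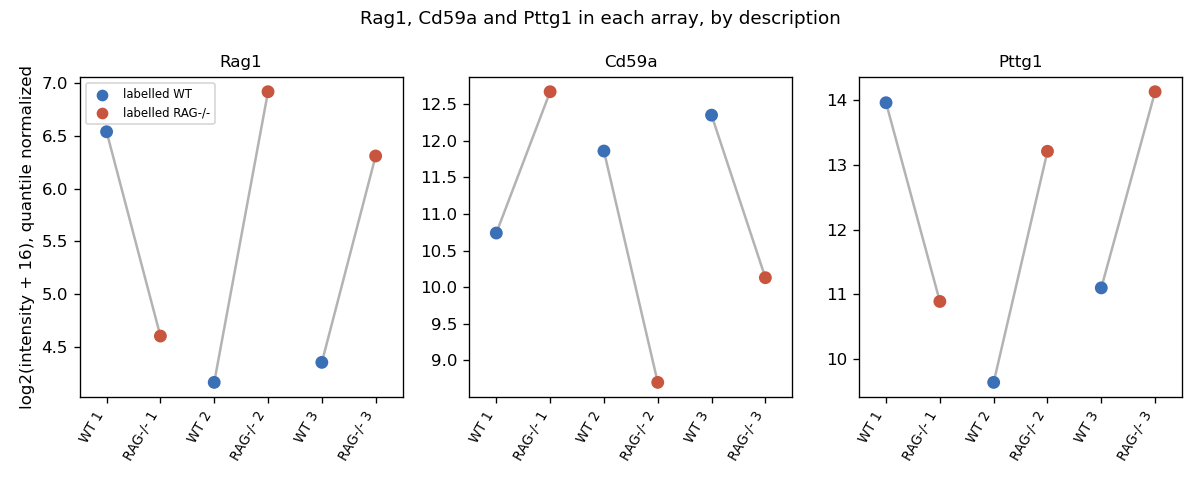
Log2(intensity + 16) after quantile normalization (vertical axis) of Rag1, Cd59a and Pttg1 in each of the 6 arrays (horizontal axis), 1 point per array, coloured by the genotype in the description, with a line joining the arrays of a pair. Each gene is shown at its brightest probe set. In pair 1 the line runs opposite to the lines of pairs 2 and 3 in each panel: Rag1 was 4.60 in RAG-/- replicate 1 and 6.54 in WT replicate 1.

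By description, no single gene separated RAG-/- from wild type choroid plexus past the threshold. With limma, 0 of 27022 probe sets passed (smallest adjusted p = 1), and 192 had an unadjusted p under 0.05 where 1351 would be expected by chance. With the pair as a block 0 passed and 636 had an unadjusted p under 0.05. Without RAG-/- replicate 2 the count was 4, namely Xist and 3 unnamed probe sets, chosen here after their values were seen. That setting leaves RAG-/- replicates 1 and 3, the arrays with Y-linked signal, as the RAG-/- group. The unnamed probe sets were bright in those arrays and dim in all others. Genotype and Y-linked signal cannot be told apart in that setting. The 3 arrays of one group all lay on one side of the other 3 in 420 genes, 229 higher and 191 lower, which is 3.1% of 13537 genes. Arrays without pairs would give 10% by chance. These arrays resembled each other within pairs, so neither 10% nor, without the block, 1351 is a fair baseline.

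The genes of this paragraph did not pass the threshold over all genes and are given for their values. Among those higher in the arrays labelled RAG-/-, the differences were 1.88 for Creb3l3, a membrane-bound transcription factor, 1.76 for Cacng7, an auxiliary subunit of neuronal channels and receptors, 1.46 for Fbxw22, 1.22 for Stoml3 and 1.12 for Epha6. The others were Dnph1, Uty, Gm20324, Mthfd2, Mrap2, Cela1 and Myl10, with differences between 0.86 and 1.73. Among those lower, the matrix proteoglycan Bgn differed by -1.76 (SE 0.42), from 11.51 ± 0.64 in wild type to 9.75 ± 0.58 in RAG-/- (SD, n = 3), and the collagens Col3a1 and Col1a2 by -1.49 and -1.08. Ebf1, a transcription factor of B cells and of mesenchyme, differed by -1.03, Xist by -3.45, Wfikkn2 by -1.24 and the Wnt inhibitor Wif1 by -1.17. Galnt15, Crtc2, Dcdc2b, Hic1 and Tmem204 differed by between -0.92 and -0.84, and the other probe set of Crtc2 went the opposite way.

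The lists of cell types and functions moved together where single genes did not pass. Camera called 12 of 29 lists, 1 higher and 11 lower in the arrays labelled RAG-/-. With an estimated correlation it called 0, with adjusted p between 0.56 and 0.767 for those 12, and fry called 0 (adjusted p of 0.953 for each of the 12). Without the block, 0 members of these 12 lists passed the threshold adjusted over the list alone and 0 over all genes. Of the 6 lists with fewer than 5 measured genes, which were not tested as lists, the sex-linked genes had 2 of 4 members past the threshold adjusted over the list alone, Xist and Uty, joined by Eif2s3y with the block, and 0 over all genes.

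Genes of fibroblasts and meninges fell as a list. All 20 measured members were lower in the arrays labelled RAG-/-, with a median of -0.99 (camera adjusted p = 6.45e-16; adjusted p = 0.56 with an estimated correlation). The list means were 10.47 ± 0.77 in wild type and 9.56 ± 0.81 in RAG-/- (SD, n = 3), a difference close to the spread between arrays (exact permutation p = 0.3). Dcn, a proteoglycan that binds collagen, differed by -1.34, and Col1a1 was at 8.94 in wild type and 7.94 in RAG-/-. With the block, Col3a1, Col1a2, Col1a1 and Dcn passed the threshold adjusted over the list alone and 0 passed over all genes. The mean difference was -1.26, -1.28 and -0.18 in pairs 1, 2 and 3. It was -0.91 over all arrays, -0.47 without WT replicate 1 and -0.44 without RAG-/- replicate 2. By title, where pair 1 turns, the median was -0.08 and the call was lost (adjusted p = 0.717).

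Oligodendrocyte genes, which build myelin, rose as a list. All 12 measured members were higher, with a median of 1.04 (camera adjusted p = 1.32e-13; adjusted p = 0.56 with an estimated correlation). The list means were 10.11 ± 0.37 in wild type and 11.06 ± 0.96 in RAG-/- (SD, n = 3; exact permutation p = 0.3). Mobp differed by 1.16, Mag, a myelin adhesion protein, by 1.31, Ermn by 1.25 and Opalin by 0.95. The mean differences were -0.45, 1.38 and 1.91 in pairs 1, 2 and 3. The mean of 0.95 over all arrays was 1.5 without RAG-/- replicate 1, 0.46 with pair 3 left out and 0.33 with array weights. By title all 12 members were again higher, with a median of 1.23 (camera adjusted p = 2.84e-22; adjusted p = 0.271 with an estimated correlation), and 9 of 12 passed the threshold adjusted over the list alone while 0 passed over all genes. Among these 9, Mal differed by 1.98, Ugt8a by 1.69, Mog by 1.54, Mobp by 1.36, Opalin by 1.31, Cnp by 1.15, Cldn11 by 1.14, Aspa by 0.81 and Mbp by 0.38. The brightest list means, 11.62 and 11.61, were those of RAG-/- replicates 2 and 3, which both readings place in the RAG-/- group.

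**Figure D2:**
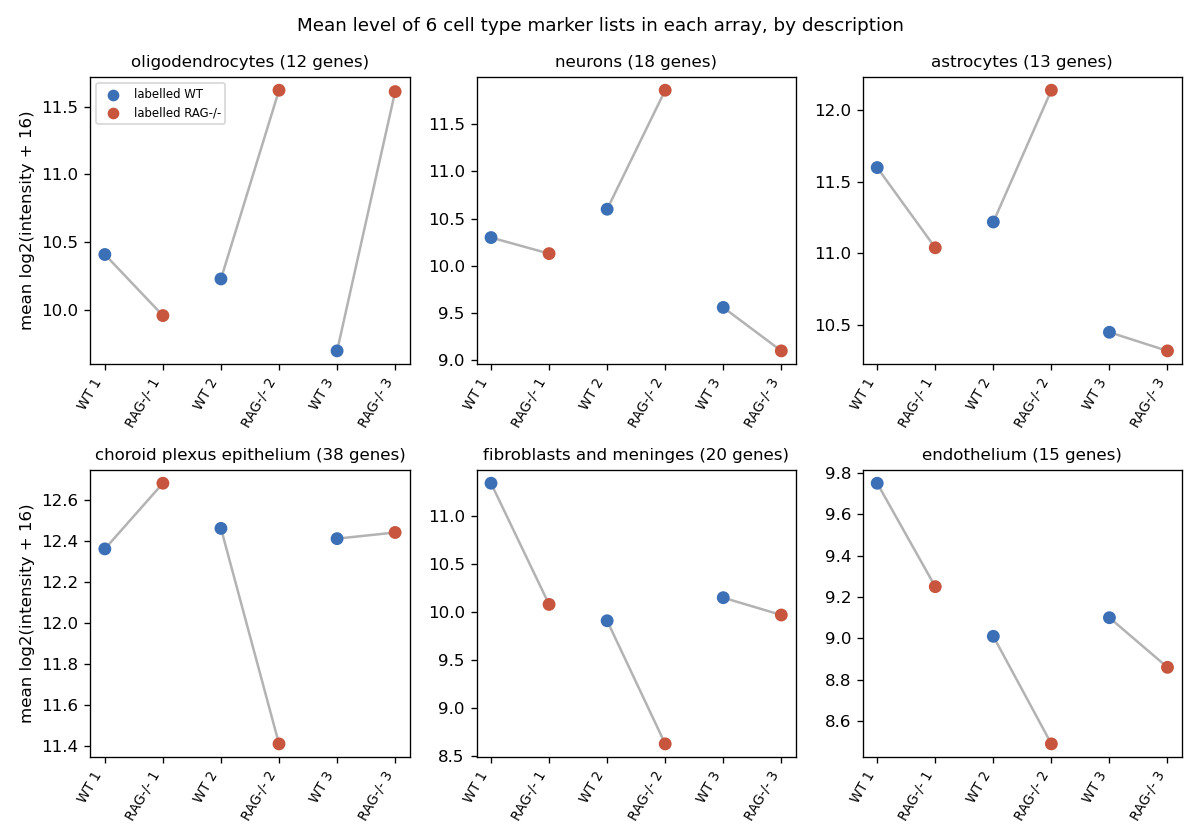
Mean log2(intensity + 16) over the measured genes of 6 cell type lists (vertical axis) in each of the 6 arrays (horizontal axis), 1 point per array, coloured by the genotype in the description, with a line joining the arrays of a pair. The oligodendrocyte mean was 11.62 in RAG-/- replicate 2 and 11.61 in RAG-/- replicate 3, and at most 10.41 elsewhere, while the choroid plexus epithelium mean was 11.41 in RAG-/- replicate 2 and at least 12.36 elsewhere.

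Choroid plexus epithelium genes fell by description, with a median of -0.26 and 36 of 38 members lower (camera adjusted p = 4.33e-05; adjusted p = 0.767 with an estimated correlation). Kcne2, a potassium channel subunit, differed by -0.38, Kl by -0.34, Abca4 by -0.46 and Col8a1 by -0.39. The direction rested on RAG-/- replicate 2. The list means in pairs 1, 2 and 3 differed by 0.32, -1.05 and 0.03, and the mean of -0.23 over all arrays was 0.15 without that array, past the threshold in the opposite direction (adjusted p = 0.00281), -0.49 without RAG-/- replicate 1 and -0.36 without RAG-/- replicate 3. The list of ion, water and solute transport fell too, with 25 of 29 members lower and a median of -0.15 (camera adjusted p = 0.023; adjusted p = 0.767 with an estimated correlation), and its mean was 0.05 without RAG-/- replicate 2 (adjusted p = 0.366) and -0.07 without WT replicate 2 (adjusted p = 0.757), against -0.30 without RAG-/- replicate 1 and -0.23 without WT replicate 3. The epithelium call was also lost with array weights (adjusted p = 0.64), and the transport call with array weights, the values as deposited or a common median (adjusted p = 0.924, 0.0682 and 0.0935; the mean as deposited stayed at -0.15). Slc22a8, an organic anion transporter, differed by -0.71, Car12 by -0.31 and Slc4a10 by -0.15. Car12, Aqp1, Folr1, Kcnj13, Kcne2, Clic6 and Slc4a5 belong to both the epithelium and the transport list, so these lists do not fall independently. By title both lists fell as well, with medians of -0.41 and -0.35 (adjusted p = 0.984 for both with an estimated correlation), including Msx1 at -0.83, Stra6 at -1.23, Slc2a12 at -0.68 and Cab39l at -0.40 of the first and Slc12a4 at -0.77 of the second. Their means of -0.44 and -0.26 by title were -0.10 and -0.09 without RAG-/- replicate 2, where the transport call was lost (adjusted p = 0.131), and the transport mean was -0.43 with pair 3 left out. RAG-/- replicate 2 also had the highest neuron and astrocyte means, 11.86 and 12.14. Snap25, a synaptic gene, was at 14.05 in it and 11.38 in RAG-/- replicate 3.

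Vascular lists fell by description. Endothelial genes had a median of -0.35, with 13 of 15 lower (camera adjusted p = 6.59e-05; adjusted p = 0.594 with an estimated correlation), including Vwf at -1.44, Kdr, a receptor for VEGF, at -0.63, Eng at -0.51 and Tek at -0.64. Genes of pericytes and smooth muscle had a median of -0.53 with 10 of 10 lower (camera adjusted p = 1.22e-04; adjusted p = 0.56 with an estimated correlation), including Pdgfrb at -0.83, Myh11 at -0.77, Kcnj8 at -0.81 and Mylk at -0.60. Both calls were lost by title (adjusted p = 0.537 and 0.904) and without WT replicate 1 (adjusted p = 0.096 and 0.16), and the endothelial call also without RAG-/- replicate 2 (adjusted p = 0.0719). The pericyte call was also lost with pair 1 left out (adjusted p = 0.0629).

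Secreted growth factors and carriers fell by description, with 23 of 31 lower and a median of -0.28, including Igfbp3 at -1.14, Rspo3 at -1.07, Igfbp4 at -0.73 and Tgfb3 at -0.89 (camera adjusted p = 0.00165, and 0.594 with an estimated correlation). In pairs 1, 2 and 3 their mean differed by -0.39, -0.41 and 0.02, and the fibroblast mean by -1.26, -1.28 and -0.18. Whether cell content carries such differences was not tested, and Igf2 belongs to both lists. Tight and adherens junction genes had 17 of 21 lower and a median of -0.26, including Cdh1 at -1.34, Ctnna1 at -0.34, Cgnl1 at -0.44 and Esam at -0.57 (camera adjusted p = 0.00938, and 0.622 with an estimated correlation). In pairs 1, 2 and 3 their mean differed by -0.09, -0.65 and 0.07, lowest in pair 2 like the epithelium mean. The junction list shares Cldn2 with the epithelium list, and Esam and Cldn5 with the endothelial list. Circadian clock genes had 12 of 16 lower and a median of -0.15, including Bhlhe40 at -0.43, Dbp at -0.22, Nr1d2 at -0.19 and Nr1d1 at -0.57 (camera adjusted p = 0.0373; adjusted p = 0.586 with an estimated correlation). All 3 calls were lost by title. Without RAG-/- replicate 2 they were lost as well, with adjusted p of 0.529, 0.95 and 0.149, and without WT replicate 1, with adjusted p of 0.218, 0.0989 and 0.0989. The junction mean of -0.22 was -0.36 without RAG-/- replicate 1. The junction call was also lost without WT replicate 2 (mean -0.23, adjusted p = 0.0597), and the circadian call without WT replicate 2 (adjusted p = 0.154) and without RAG-/- replicate 1 (adjusted p = 0.238). Both were lost with no filter on dim probe sets (adjusted p = 0.0735 for each, with a junction mean of -0.18). The junction call was also lost with array weights (mean -0.12, adjusted p = 0.287). The circadian call was lost with the values as deposited, a common median or pair 1 left out (adjusted p = 0.062, 0.0663 and 0.267). The circadian mean of -0.16 stayed between -0.21 and -0.12 without single arrays, and at -0.16 with no filter and as deposited.

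Of the immune lists, 3 fell by description. Interferon-stimulated genes had 22 of 29 lower and a median of -0.20 (camera adjusted p = 0.00692; adjusted p = 0.767 with an estimated correlation), including Irf1 at -0.61, Gbp7 at -0.62, Igtp at -0.44 and Gbp3 at -0.41. That list fell by title too, with a median of -0.33 (adjusted p = 0.984 with an estimated correlation), including Irf9 at -0.61 and Rtp4 at -0.84. Genes of granulocytes and mast cells had 9 of 11 lower and a median of -0.50 (camera adjusted p = 0.00804; adjusted p = 0.696 with an estimated correlation), including Camp, an antimicrobial peptide of neutrophils, at -1.59, Elane at -0.40, Tpsab1 at -0.49 and Kit at -0.64. Their list means followed the pairs, at 6.98 and 6.57 in pair 2 and between 8.23 and 9.59 in the other arrays. Complement and acute phase genes had 10 of 12 lower and a median of -0.48 (camera adjusted p = 0.036; adjusted p = 0.767 with an estimated correlation), including Serping1 at -1.04, A2m at -0.63 and C1ra at -0.64, while Saa3 was at 1.15. Each of these calls by description was lost without WT replicate 1 (adjusted p = 0.228, 0.818 and 0.62) and without RAG-/- replicate 2 (adjusted p = 0.595, 0.529 and 0.817), and by title the granulocyte list had a mean of 0.19. The interferon call was also lost without WT replicate 3 (adjusted p = 0.086) or RAG-/- replicate 3 (adjusted p = 0.0638), and the complement call without RAG-/- replicate 3 (adjusted p = 0.294), where the means, -0.24 and -0.31 without that array, were no smaller in size than over all arrays (-0.21 and -0.31). Without RAG-/- replicate 2 the interferon and complement means both turned to 0.06. The granulocyte call was also lost with no filter on dim probe sets or pair 1 left out (mean -0.43 and -0.39, adjusted p = 0.184 and 0.323). The complement call was lost with no filter or array weights (mean -0.25 and -0.17, adjusted p = 0.0944 and 0.37), and the interferon call with array weights (adjusted p = 0.878). Where these calls stood, the interferon mean of -0.21 was -0.45 without RAG-/- replicate 1 and -0.39 without WT replicate 2, the complement mean of -0.31 was -0.60 and -0.58, and the granulocyte mean of -0.68 was -1.38 without WT replicate 2. By title the interferon call was lost without RAG-/- replicate 1, RAG-/- replicate 2 or WT replicate 3 (adjusted p = 0.216, 0.677 and 0.0901), and its mean of -0.27 was -0.50 and -0.46 without WT replicates 1 and 2. Without WT replicate 3 the list stayed lower by title, so the lost call there does not show that the difference went away.

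Genes of T and B cells, whose mature forms RAG-/- mice lack, were mostly dim in both groups, and none of those named here was lower past the threshold in the arrays labelled RAG-/-. Of the genes with a probe set of their own, 2 of 19 T cell genes and 8 of 18 B cell genes passed the filter on dim probe sets, as did 4 of 6 immunoglobulin genes. The T cell and immunoglobulin lists were then too small to test, as was that of NK cells, with 4 of 13. Cd3e, a subunit of the T cell receptor complex, was at 5.19 ± 0.14 in wild type and 5.40 ± 0.72 in RAG-/- (SD, n = 3), at the 22.3 percentile. The 8 measured B cell genes had a median difference of 0.12 (camera adjusted p = 0.822). Ighm, the heavy chain of IgM, was not dim at its brightest probe set, which lay at the 76.7 percentile. That probe set was at 8.45, 11.27 and 8.28 in RAG-/- replicates 1, 2 and 3 and at 8.24, 7.83 and 9.94 in the wild type arrays. Its difference of 0.67 was -0.30 without RAG-/- replicate 2. The 11 probe sets of Ighm went both ways. Igha and Jchain, also of the immunoglobulin list, were chosen after their values were seen. At its dim probe sets Igha was at 7.69 and 7.78 in RAG-/- replicate 1 and at most 5.87 and 5.68 elsewhere. Its brightest was at 7.30 there and 7.19 in RAG-/- replicate 2. Jchain was at 5.65, 6.32 and 6.34 in the libraries titled RAG and 7.18, 6.50 and 6.93 in the others. It differed by -0.76 by title and 0.26 by description and did not pass over all genes. For dim genes such as Cd3e a loss was not detectable at this signal. Antigen presentation did not pass the threshold, with medians of -0.12 for MHC class II (adjusted p = 0.589) and -0.22 for MHC class I (adjusted p = 0.176), Cd74 at -0.16 and H2-Aa at -0.49 for its brightest probe set. Macrophage and microglia genes had a median of -0.03 (adjusted p = 0.473). The list of genes flanking the Rag locus on chromosome 2 was not called by description (median -0.02, adjusted p = 0.89) or by title (median 0.02 and mean -0.01, adjusted p = 0.955).

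By title, 0 probe sets passed without the block (limma, smallest adjusted p = 0.914, 332 with an unadjusted p under 0.05), and 640 genes, 4.7%, separated the groups. The 10% for arrays without pairs is no fair baseline here either. With the block, 1 passed, for Pttg1, known as securin, an inhibitor of chromosome separation (difference 3.23, higher in all 3 libraries titled RAG, adjusted p = 0.012), and 1118 had an unadjusted p under 0.05. That was 1 call in 4 fits. Over the alternatives the adjusted p of Pttg1 ran from 1.27e-05 to 0.914, while its difference stayed between 3.12 and 3.32. The call was lost with pair 1 left out (difference 3.32, adjusted p = 0.222) and with no intensity trend or no block (difference 3.23 in both, adjusted p = 0.264 and 0.914). A second bright probe set of Pttg1 differed by 3.28. Cd59a, a complement inhibitor encoded near Rag1 and Rag2, differed by -2.44 and did not pass over all genes (adjusted p = 0.406 with the block, and from 0.000938 to 1 over the alternatives), though it passed adjusted over the list of flanking genes alone with the block, as 1 of 36. Its other probe set differed by -0.54.

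Other genes by title did not pass over all genes. Among those higher with the smallest p, Olig2, a transcription factor of the oligodendrocyte lineage, differed by 1.34, Tmcc3 by 1.24 and Sulf2 by 1.34, and among those lower Mcoln3 by -1.28, Tcf21 by -1.15 and Spint2 by -0.76. Of Sulf2 and Tcf21, 1 other probe set each went the opposite way. Rarres2, Ccdc153 and Tmem212 of the ependyma list, the ciliated lining of the ventricles, differed by 1.38, 1.29 and 1.34 and passed the threshold adjusted over the list alone, though the list did not (median -0.07, mean 0.09, adjusted p = 0.537). With the block, all 12 oligodendrocyte genes, Drd1, Pde10a and Gng7 of the striatal list (1.21, 1.15 and 1.03) and Fos and Ccn1 of the immediate early list (1.18 and 1.03) also passed adjusted over their list alone, and 0 of them over all genes. Camera called 8 of 29 lists by title, 4 of them shared with the calls by description and all 4 in the same direction. The other 4 were higher by title and not called by description. They were striatal neurons (median 1.04, Pde10a at 1.15, Tac1 at 1.90), astrocytes (0.40, Gja1 at 0.54), immediate early genes (0.48, Fos at 1.18) and neurons (0.34, Camk2a at 0.86), with adjusted p of 0.271, 0.984, 0.984 and 0.984 with an estimated correlation. The neuron mean of 0.32 turned to -0.40 without RAG-/- replicate 2 (adjusted p = 0.0143), was lost without WT replicate 3 or RAG-/- replicate 1 (mean 0.05 and 0.37, adjusted p = 0.63 and 0.054), and was 0.64 without WT replicate 2 and 0.97 without RAG-/- replicate 3. Its call was also lost with no filter on dim probe sets, the values as deposited, a common median, array weights or the mean of a gene's probe sets (mean 0.32, 0.29, 0.25, 0.08 and 0.32, adjusted p = 0.0801, 0.0824, 0.0584, 0.451 and 0.05). The astrocyte call, with a mean of 0.45, was lost without RAG-/- replicate 2, WT replicate 3 or WT replicate 1 (adjusted p = 0.756, 0.335 and 0.0642). Without WT replicate 1 the list stayed higher in the arrays titled RAG, and without RAG-/- replicate 3 the mean was 0.96. The immediate early call, with a mean of 0.48, was lost without WT replicate 1, WT replicate 2 or RAG-/- replicate 3 (adjusted p = 0.674, 0.409 and 0.454). Its mean was 1.10 without RAG-/- replicate 2.

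The lists not named so far, namely those of thalamus, habenula and pineal, chemokines and adhesion, proliferation, chaperones, oxidative phosphorylation, ribosomal proteins, and metallothioneins and oxidative stress, were not called by description, with adjusted p between 0.0856 and 0.815, or by title, with adjusted p between 0.0606 and 0.966. With the block, the chaperone list passed by title (adjusted p = 0.0482; adjusted p = 0.931 with an estimated correlation). By description, the lists of ependyma, neurons, striatal neurons, astrocytes and immediate early genes were not called either (adjusted p = 0.359, 0.161, 0.487, 0.589 and 0.815). Among lists not called, the median and mean differed in sign by description for metallothioneins and oxidative stress (0.02 and -0.04), and by title for B cells (-0.05 and 0.02), thalamus, habenula and pineal (-0.08 and 0.05) and proliferation (0.02 and -0.02), while the circadian list tested higher with a median of -0.04. Erythroid genes, with 4 measured of 10, were too few to test.

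The X-linked transcript Xist, made from the inactive X of females, and Y-linked genes differed between arrays of the RAG-/- group. Xist was at 9.04, 12.20 and 7.43 in RAG-/- replicates 1, 2 and 3 and at 13.01 ± 0.16 (SD, n = 3) in wild type. Eif2s3y, a Y-linked gene, was at 9.47 and 9.76 in RAG-/- replicates 1 and 3 and at no more than 5.76 in the other 4 arrays. The ratio of 5' to 3' signal of Actb, a sign of RNA integrity, was 0.0381 and 0.0414 in pair 3 and between 0.221 and 0.334 in the other pairs.

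**Figure D3:**
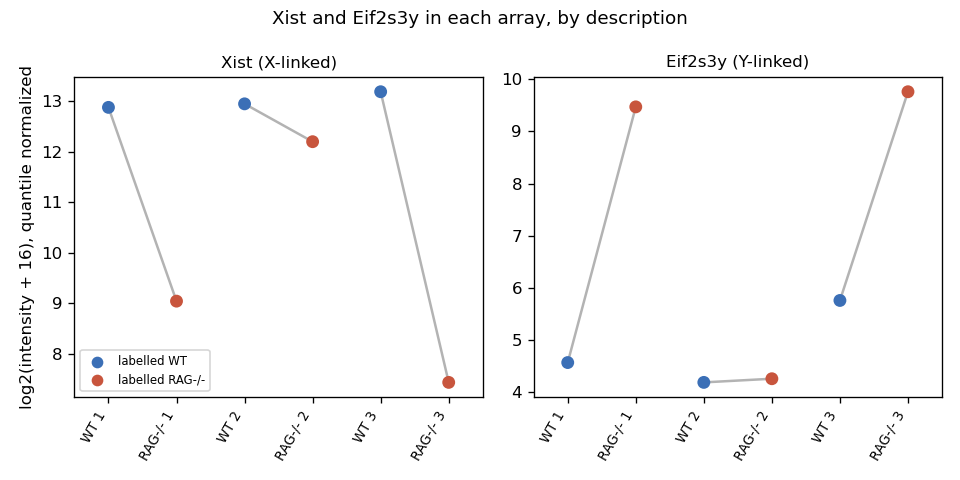
Log2(intensity + 16) after quantile normalization (vertical axis) of Xist and Eif2s3y in each of the 6 arrays (horizontal axis), 1 point per array, coloured by the genotype in the description, with a line joining the arrays of a pair. Eif2s3y was 9.47 and 9.76 in RAG-/- replicates 1 and 3 and at most 5.76 in the other 4 arrays.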

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

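The settings that leave out pair 2, pair 3 or both arrays with Y-linked signal, that join the titles with the replicate block, and each of those run with groups by title were chosen after the data had been seen. Signal over background limits Rag1, Rag2 and most T and B cell genes, though not the bright probe sets of Ighm. Leaving out arrays leaves fewer samples, and without both arrays with Y-linked signal 1 array labelled RAG-/- remains, which is assumed to vary like the others. These settings do not test the cause of a difference. Tests of some candidate causes are given under the other observations.

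By description the count of probe sets past the threshold was 0 with limma under each other setting run, the replicate block included (636 at an unadjusted p under 0.05), except 4 without both arrays with Y-linked signal (Tph2, Slc6a4, Ddc and Slc18a2, bright in the remaining array alone), 2 with pair 2 left out, 1 by title with the replicate block, and 0 to 4 without single arrays, the 4 without RAG-/- replicate 2. The count of lists, 12, was 0 with an estimated inter-gene correlation and between 8 and 16 without single arrays. Apart from single members adjusted over their list alone, the replicate block changed no call by description. Rag1, at 0.93, kept its sign, at 0.43 to 1.69 without single arrays, 2.39 with pair 1 left out (unadjusted p = 0.00198, adjusted p = 1), 0.01 and 0.41 with pairs 2 and 3 left out, 1.91 and 0.43 with a pseudocount of 1 and 64, 0.23 with array weights, 1.92 without the arrays with Y-linked signal, and 2.22 by title with and without the replicate block. Rag2, at 0.05, was -0.08 with a pseudocount of 64, -0.46 with pair 1 left out, -0.68 by title with and without the replicate block, -0.04 with pair 2 left out, -0.55 without the arrays with Y-linked signal, and -0.43 to 0.90 without single arrays.

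By title with the replicate block, the count of 1 was 2 with a common median, 0 with no intensity trend, 2 with array weights, 0 with no replicate block, and 0, 15 and 1 with pairs 1, 2 and 3 left out. The count of lists by title, 8, was 16 with array weights, 0 with an estimated inter-gene correlation, 9 with the replicate block and 6 to 13 without single arrays.

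Some lists turned direction. Choroid plexus epithelium, by description, had a mean of 0.15 without RAG-/- replicate 2, with -0.49 as the lowest without a single array, 0.17 with pair 2 left out and 0.06 with array weights. With pair 2 left out, this list and the transport list passed in the opposite direction (camera adjusted p = 0.000158 and 0.00383). Transport genes had 0.05 and -0.30 as highest and lowest without single arrays and 0.13 with pair 2 left out, interferon-stimulated genes 0.06 and -0.45, and complement genes 0.06 and -0.60, without single arrays. Junction genes had -0.01 and -0.36 without single arrays and -0.01 with pair 2 left out, circadian genes -0.01 by title with and without the replicate block, and transport genes 0.00 with array weights, where camera's direction turned without the sign of the mean or with a mean near 0. Granulocyte and mast cell genes had 0.19, and pericyte genes 0.05, by title with and without the replicate block. By title, interferon-stimulated genes had 0.07 with array weights, and neurons -0.40 and 0.97 as lowest and highest without single arrays and -0.12 with pair 2 left out. The oligodendrocyte list was called under each setting except the estimated correlation, with means between 0.33 and 1.65, and the fibroblast list under each except that and both fits by title. Of the genes named by description, 13 of 75 changed sign by title, 9 of 73 with pair 2 left out and 8 of 73 without RAG-/- replicate 2, none of these past the threshold, and Xist passed without RAG-/- replicate 2 (-4.83, adjusted p = 0.0414). By description, leaving out that array or pair 2 leaves only arrays with Y-linked signal in the RAG-/- group. Genotype and that signal cannot be told apart there. Of 57 genes named by title, 1 changed sign without RAG-/- replicate 2 and 1 with pair 2 left out. Over both readings, 92 list values kept their direction and lost the call, 337 kept both and 19 turned. Leaving out pair 2, an added setting, ended the calls of interferon, complement, junction, growth factor and circadian genes by description and of transport, neurons and astrocytes by title. Leaving out pair 3 ended those of interferon and complement genes by description (means of -0.21 and -0.31 were then -0.17 and -0.37) and of interferon and immediate early genes by title. The interferon list stayed lower by title without pair 3, so the lost call does not show that the difference went away. Without the arrays with Y-linked signal, the pericyte and circadian means of -0.53 and -0.16 were -0.60 and -0.23.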

Other observations

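Transcripts of single brain regions and of the pituitary differed strongly between arrays. These genes were chosen after their values were seen. The serotonin neuron genes Tph2, Slc6a4 and Slc18a2 were at 13.82, 13.85 and 12.44 on the log2 scale in RAG-/- replicate 2 and at no more than 6.42, 6.16 and 6.20 in the other 5 arrays, and Ddc, an enzyme of serotonin and dopamine synthesis, was at 14.52 there against at most 8.55. Growth hormone, Gh, was at 12.37 in WT replicate 3 and between 6.68 and 9.40 elsewhere at its brightest probe set, and Prl, prolactin, at 11.65 against at most 7.95. The Purkinje cell genes Pcp2 and Car8 ran from 7.15 and 8.91 in WT replicate 3 to 12.55 and 13.34 in WT replicate 2. The neutrophil gene S100a8 was at 7.60 and 6.62 in pair 2 and between 10.79 and 13.21 in the other arrays.

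The tests of the 3 patterns below and the counts of splits and pair orientations for probe sets were chosen after the results had been seen. The counts of splits for lists were set out before they were seen.

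At the brightest probe set of each gene, Rag1, Cd59a and Pttg1 parted the arrays by title. A candidate explanation is that pair 1 carries the genotypes of its titles. The second bright Pttg1 probe set parted them as well. The other Cd59a probe set overlapped, at 10.22, 8.46 and 9.87 in the libraries titled RAG and 10.71, 9.75 and 9.71 in the others. A dim Pttg1 probe set overlapped too, with RAG-/- replicate 2 at 4.76 and WT replicate 2 at 5.39. Noise of dim probe sets is argued against for Cd59a and Pttg1, whose means lay at or above the 92.2 percentile, but not settled for Rag1, whose 3 brighter arrays exceeded the highest intensity of an unspiked bacterial control, 45.7, while its mean lay at the 27.1 percentile. Over the 4 ways to orient the pairs, the title orientation had 18 probe sets at an unadjusted p under 0.001 against 13, 10 and, by description, 5, but chance alone gives 27, and at an unadjusted p under 0.05 its 1118 lay below the 1502 with pair 2 turned and the 1351 expected, so these counts leave the explanation open. Among the 50 measured genes nearest Rag1 (GRCm38.p6 gene order) 7 besides Cd59a had an unadjusted p under 0.05 by title, as many as in a share of 0.007 of windows, which would fit linked genes that differ with the titled genotype. The windows overlap, so that share is not a p-value. Of the 7 genes, Slc1a2 and Lrrc4c were higher by title (0.99 and 0.85) and the others lower. Slc1a2 also belongs to the astrocyte list, which was called higher by title. The count was first made with Cd59a (share 0.001) and repeated without it because Cd59a belongs to the pattern. The list of flanking genes fixed in advance had a fry p of 0.105 for change in either direction in the same blocked fit, which decides neither way. The share of shuffled orders with a window as crowded as the fullest was 0.365. That leaves runs of neighbours open, as it does an effect of genotype, strain or labels on these genes.

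The oligodendrocyte list was higher and the fibroblast list lower in the arrays labelled RAG-/-. For the oligodendrocyte difference of 1.91 in pair 3, the arrays differed in the 5' to 3' ratios of Actb and Gapdh by at most 0.15 of the range over arrays. Both arrays had the lowest ratios of all (Actb 0.0381 and 0.0414, Gapdh 0.0635 and 0.0875). Pair 3 thus set that range itself, so the small share cannot exclude RNA integrity. For the other pairs and lists RNA integrity stays open too. The largest difference of the Actb ratio within a pair was 0.19 of its range on the log2 scale and 0.38 on the linear scale. More brain tissue of all kinds could account for pair 2, where the neuron list differed by 1.26 (SE 0.21 over genes). In pair 3 the neuron list differed by -0.46 (SE 0.14 over genes) while the oligodendrocyte list was higher, opposite to that explanation. Each SE takes the genes of a list as independent and compares single arrays. It does not measure the spread between dissections, so the explanation is not excluded in pair 3. A piece of adjacent tissue richer in white matter in pair 3, and an effect of genotype, stay open and were not tested.

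Y-linked genes were bright in RAG-/- replicates 1 and 3, where all 3 measured Y-linked genes of the list were brighter than in the other 4 arrays and Xist was dimmer. Animals of different sex between the arrays may account for this, and those 3 genes fit it. By description sex then differs within the RAG-/- group, and in pairs 1 and 3 it runs with genotype. By title it runs opposite to genotype in pair 1 and with it in pair 3. Rag1, Cd59a and Pttg1 were compared at their brightest probe sets. For 3 of 3 genes the array with Y-linked signal differed from its partner in opposite directions in pairs 1 and 3. Pttg1 differed by -3.08 and 3.03. A difference that follows sex alone would keep its direction. The opposite signs follow from the parting by title itself, so they restate the pattern and are no separate test.

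The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. By description 0 probe sets passed, with 0 as the highest other, and since any split gives at least 0, the 10 of 10 that did so say nothing. For lists, 4 of 10 splits gave at least the 12 called by description, and 7 of 10 at least the 8 called by title, with a highest other count of 19 for both. The 4 ways to orient the pairs are too few as well, and 1 of 4 gave the 1 probe set seen by title with the block, with 0 as the highest other. Among the 4 splits that part all 3 pairs, between 192 and 332 probe sets had an unadjusted p under 0.05, with the description the lowest and the title the highest, and the lists called were 12 by description, 8 by title, 6 and 9. With the block, the 4 orientations gave 12 lists by description, 9 by title, 8 and 10. The 6 splits that part 1 pair gave 831 to 3944 probe sets and up to 19 lists, which points to a structure of the samples by pair.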
